A study of Macaca fascicularis with 8 samples.

How the data were processed

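Total RNA of macTSC#2 and macTSC#4, extracted with TRI Reagent per the labels' protocols, was sequenced after 4 days with or without CHIR99021. The 8 libraries fall into 4 groups of line and treatment, taken from the sample titles, with 2 libraries per group and no library left out. One table holds all of them, and its columns were assigned to libraries by their names, with 0 columns of other origin. HISAT2, StringTie, featureCounts and DESeq2 are named, per the submitters' processing notes, without versions or settings. The genome build, the annotation, the strandedness of the libraries and the handling of reads that match several genes are not given in the sources used here. Gene expression values are the authors' TPM, per the file headers, which scale each library to the same total after division by gene length. The log2 fold change and the adjusted p-value of the authors' own comparison with against without CHIR99021 stand in the same deposited table, with the authors' call of each gene, and both come from DESeq2 per the file headers. They are used only beside the results computed here.

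The table lists 32374 genes, of which 23626 are above 0 in some library and 16584 carry a symbol of their own. Biotype words in the symbol column were not used as names, and of the 20 symbols given to 2 genes the one with the higher mean kept it. Genes are identified by the symbol and Ensembl identifier given there, and no coordinates are reported, because no build is named. The gene table of the RefSeq assembly at hand paired none of these Ensembl identifiers with a gene and was not used further.

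Within a gene, TPM values are whole multiples of what 1 read is worth, apart from 1 factor per library. The factors were taken from the commonest ratio of low values between libraries, and whole reads were worked back for 23626 of 23626 genes, within a tolerance of 0.00010 reads (largest deviation 2.33e-10). A common divisor of all of a gene's reads cannot be seen this way, so the reads of genes with few values are lower limits. The reads sum to 45163472 to 53941563 per library, a depth that differs little between groups. They served to describe depth and for an alternative fit, not for the main results. Replicates correlated with Pearson's r of 0.982 to 0.988 over log2 values, and reads differed by more than sampling noise within every group (chi-square per degree of freedom 7.58 to 33.8), so each library was counted as 1 replicate.

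The design fixed before the data were examined assumed counts. The file held TPM, so the test planned for normalised values was used instead: limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with a fit of the 4 group means over all 8 libraries, an intensity trend in the prior variance and 4 residual degrees of freedom. Genes with a mean of 1 TPM or more in at least 1 group were tested, and p-values were adjusted by Benjamini-Hochberg over the 16902 genes. The contrasts were the effect of CHIR99021 in the mean of both lines, the effect in each line, the difference of these effects (macTSC#4 minus macTSC#2) and the difference between the lines in the mean of both treatments. A fold change on this scale understates the change of genes near 1 TPM. Nothing says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, technical or not.

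Gene lists for Wnt signalling, trophoblast lineages, cell programs and other cell types were fixed before the data were examined. Lists with 5 or more tested members were compared with all other genes by limma's camera, adjusted over 18 lists. This was done with a preset correlation of 0.01 and again with an estimated correlation. The estimated setting passed no list in any contrast (lowest adjusted camera p 0.313 to 0.594), so failing it does not set a list apart. A second test, limma's fry, asks whether the genes of a list move one way, not whether they differ from other genes. Lists of other cell types, of Y-linked genes and of mitochondrial mRNAs were counted without a set test. The genes named in the text follow a rule fixed at the same time. It takes a panel of 16 genes whatever their values, the 10 highest and 10 lowest changes of the mean effect with the same direction in both lines, up to 4 members per list with the largest change past the threshold, 5 genes each way for the difference of effects and for the lines, and the Y-linked genes, each with a mean of 1 TPM or more in a group where it was ranked. Other list members, the genes of the contractile list the genes named beside RPL37 and the differences of effect given for MMP1, MMP12 and SERPINE1 were chosen after their values were seen.

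The fit was tested on simulated reads drawn with the real mean of each line and the real depths, with 200 genes changed per comparison. Their spread was averaged over the 4 groups and over genes of like expression. The unequal spread of the real groups was thus not simulated, and the error rates below hold for even spread only. Over 16535 genes, the mean effect was recovered for 73.7% of genes changed 2-fold and 55.0% of those changed 1.5-fold, with 12 of 16141 unchanged genes called. The difference of effects was recovered for 28.9% and 1.02%, with 2 of 16141 unchanged genes called. Alternatives were median-of-ratios and upper-quartile scaling, no filter and a stricter filter on low values, a pseudocount of 0.1, the replicate number as a block, an additive fit, fits of 1 line alone, a fold threshold, and leaving out each library in turn. After the data were seen, a limma voom fit on the worked-back reads and a fit without a line term were added. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the figures.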

Results

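RNA sequencing libraries were made from macTSC#2 and macTSC#4, a pair of trophoblast stem cell lines of the cynomolgus monkey (Macaca fascicularis). Trophoblast stem cells can give rise to the syncytiotrophoblast, the fused hormone-producing layer of the placenta, and to invasive extravillous trophoblast. Each line was cultured for 4 days with or without CHIR99021, an inhibitor of glycogen synthase kinase 3 that stabilises beta-catenin and so activates canonical Wnt signalling. The series title names Wnt activation and a syncytiotrophoblast progenitor state, so the genes of Wnt signalling and of the trophoblast lineages are given first. The 4 groups of line and treatment held 2 libraries each, with 45163472 to 53941563 reads on genes per library, worked back from the expression values. Expression is given as TPM, the share of a library's transcripts after division by gene length, as mean ± SD of the libraries of a group, and changes are log2 fold changes of TPM + 1 with their standard error (SE). The first principal component held 60.8% of the variance and separated the lines, and the second held 19.5% and separated cells with CHIR99021 from cells without it.

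AXIN2, TNFRSF19, ZNRF3, TCF7 and NOTUM, targets of Wnt signalling, rose with CHIR99021 in both lines. AXIN2 (ENSMFAG00000000055), a scaffold of the beta-catenin destruction complex, rose from 26.1 ± 0.24 to 64.4 ± 0.74 TPM (SD, n = 2) in macTSC#2 and from 16.9 ± 0.54 to 52.6 ± 3.1 TPM in macTSC#4. TNFRSF19, a receptor of the tumour necrosis factor family, rose from 4.28 ± 0.27 to 67.2 ± 4.2 TPM in macTSC#2 and from 4.08 ± 0.55 to 50.6 ± 1.4 TPM in macTSC#4. ZNRF3, a ubiquitin ligase that removes Wnt receptors from the cell surface, and TCF7, a transcription factor that binds beta-catenin, rose by 1.70 ± 0.078 (SE) and 1.60 ± 0.12 (SE) on the log2 scale in the mean of both lines. LEF1, a relative of TCF7, rose by 0.38 ± 0.076 (SE) in that mean (adjusted p = 0.00756) and did not pass the test in macTSC#4 alone (0.35, adjusted p = 0.0582). NOTUM, a secreted enzyme that inactivates Wnt ligands, rose from 4.21 ± 0.21 to 39.1 ± 1.2 TPM in macTSC#2 and from 20.4 ± 0.16 to 29.4 ± 2.2 TPM in macTSC#4. Of the 14 tested members of the Wnt target list, 7 rose, 3 fell and 4 did not pass the test, and 11 passed when adjusted over the list alone. By line, 7 rose and 2 fell in macTSC#2, and 5 rose and 1 fell in macTSC#4. The members that fell were the secreted Wnt antagonist DKK1, the receptor FZD7 (-0.45) and the cyclin CCND1 (-0.30). DKK1 changed by -1.04 in the mean, with -0.71 in macTSC#2 and -1.36 in macTSC#4, both past the test. FZD7 did not pass the test in macTSC#4 alone (adjusted p = 0.0799), and CCND1 passed in neither line alone (0.0601 in macTSC#2 and 0.164 in macTSC#4). LGR5, a further target, stayed at or below 0.103 TPM in the mean of every group and was not tested. The list as a set stood higher than other genes (camera, adjusted p = 0.0074; adjusted p = 0.32 with an estimated correlation).

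Some Wnt ligands and receptors fell with CHIR99021. WNT7A fell from 23.5 ± 0.45 to 5.16 ± 0.43 TPM (SD, n = 2) in macTSC#2 and from 19.1 ± 0.36 to 4.18 ± 0.61 TPM in macTSC#4. WNT4 fell by 1.29 on the log2 scale, the secreted antagonist SFRP2 changed by -1.06 ± 0.16 (SE) and the receptor FZD8 by -0.79 ± 0.15 (SE). FZD8 did not pass the test in macTSC#4 alone (adjusted p = 0.124). Of 18 tested members, 1 rose, 9 fell and 8 did not pass the test, and the member that rose was WLS (0.23), which carries Wnt ligands to the cell surface. By line, 8 fell in macTSC#2 and 4 in macTSC#4. The number past the threshold in the mean was 11 when adjusted over the list alone. The set stood lower than other genes (camera, adjusted p = 0.0032; adjusted p = 0.32 with an estimated correlation).

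**Figure D1:**
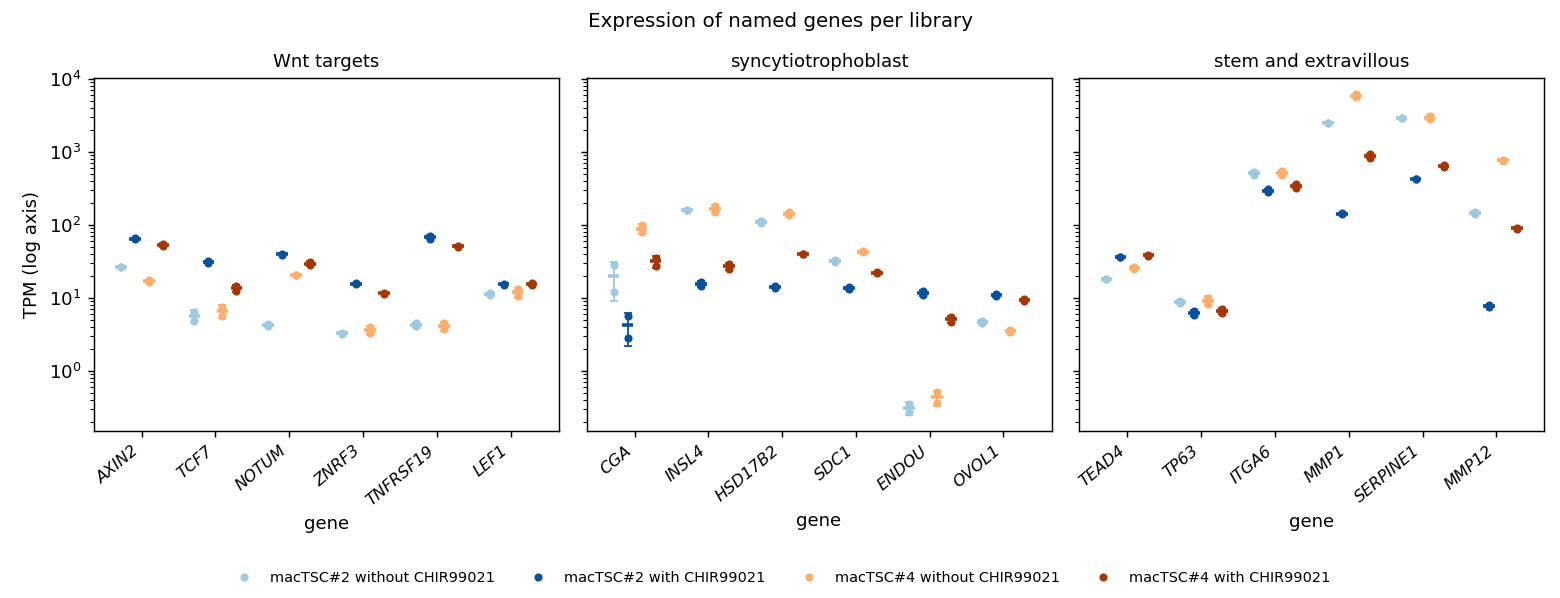
TPM per library on a log axis for 18 genes in 3 panels, with points for libraries, short horizontal lines for group means and error bars for the SD (n = 2), coloured by line and treatment. AXIN2, TCF7, NOTUM, ZNRF3 and TNFRSF19 stand higher and CGA, INSL4, MMP1 and SERPINE1 lower with CHIR99021 in both lines, with SERPINE1 at 2874 TPM without and 422 TPM with CHIR99021 in macTSC#2.

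Syncytiotrophoblast genes moved in both directions. CGA, the common alpha subunit of chorionic gonadotropin, fell from 19.9 ± 11 to 4.22 ± 2.0 TPM (SD, n = 2) in macTSC#2 and from 87.9 ± 14 to 31.3 ± 5.7 TPM in macTSC#4 (log2 fold change in the mean of both lines -1.71, adjusted p = 0.00309). INSL4, an insulin-like peptide of the placenta, fell from 159.6 ± 2.1 to 15.6 ± 1.5 TPM in macTSC#2 and from 165 ± 19 to 26.9 ± 2.6 TPM in macTSC#4. HSD17B2, which oxidises oestradiol, changed by -2.35 ± 0.046 (SE), and the placental galectin LGALS13 by -2.11 ± 0.15 (SE). ENDOU, an endoribonuclease of the placenta, rose from 0.310 ± 0.061 to 11.6 ± 1.1 TPM in macTSC#2 and from 0.433 ± 0.10 to 5.10 ± 0.57 TPM in macTSC#4. The placental growth factor PGF rose as well (0.79). Of the 24 tested genes of hormones, secreted proteins and steroid synthesis, 6 rose, 11 fell and 7 did not pass the test, with 18 past the threshold when adjusted over the list alone. The set was not called by camera (adjusted p = 0.135), but it passed by fry (adjusted p = 1.38e-05). CYP19A1, the aromatase, was listed at 0 TPM in all macTSC#2 libraries and at 0.0832 ± 0.065 TPM without and 1.06 ± 0.21 TPM with CHIR99021 in macTSC#4, where it rose by 0.93 ± 0.25 (SE) on the log2 scale with an adjusted p of 0.0387. The difference of its effect between the lines did not pass the test (adjusted p = 0.329). Its adjusted p for the mean effect was 0.0839, and 0.00369 without a filter on low values. LGALS13 belongs to a family of close paralogs, and how reads matching several genes were handled is not given in the sources used here.

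Among genes of cell fusion and syncytiotrophoblast regulation, the transcription factor OVOL1 rose from 4.66 ± 0.26 to 10.8 ± 0.53 TPM (SD, n = 2) in macTSC#2 and from 3.5 ± 0.13 to 9.35 ± 0.35 TPM in macTSC#4. The iron exporter SLC40A1 rose by 1.49 ± 0.10 (SE) on the log2 scale. SDC1, a proteoglycan of the syncytiotrophoblast surface, fell from 31.8 ± 1.0 to 13.4 ± 0.57 TPM in macTSC#2 and from 42.9 ± 0.74 to 22 ± 0.28 TPM in macTSC#4, and carboxypeptidase CPM changed by -1.04 ± 0.17 (SE). CPM did not pass the test in macTSC#4 alone (adjusted p = 0.0592). The nuclear receptor PPARG fell as well (-0.83). GCM1, which drives fusion, rose from 4.08 ± 0.99 to 7.12 ± 1.7 TPM in macTSC#2 (log2 fold change 0.67, adjusted p = 0.0335) and did not pass the test in macTSC#4 (-0.073, adjusted p = 0.821) or in the mean of both lines (0.30, adjusted p = 0.111). The difference of its effect between the lines did not pass either (adjusted p = 0.266). ERVFRD-1, the envelope gene syncytin-2 of the retroviral fusion machinery, stayed at or below 0.911 TPM in the mean of every group and was not tested. Of 25 tested members, 7 rose, 14 fell and 4 did not pass the test, and 23 passed when adjusted over the list alone. The set did not pass (camera, adjusted p = 0.0693), but it passed without a filter on low values (adjusted p = 0.0282) and without replicate 2 of macTSC#2 with CHIR99021 (adjusted p = 0.0422). Adjusted p was 0.32 with an estimated correlation.

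Genes of stem cells and villous cytotrophoblast also went both ways. TEAD4, a transcription factor of early trophoblast, rose from 17.8 ± 0.030 to 36.5 ± 0.20 TPM (SD, n = 2) in macTSC#2 and from 25.5 ± 1.4 to 38.0 ± 1.3 TPM in macTSC#4. PAGE4, a cytotrophoblast marker, changed by 2.94 ± 0.14 (SE), the homeobox gene MSX2 by 1.99 ± 0.087 (SE) and the endocytic receptor LRP2 by 1.35 ± 0.15 (SE). TP63, a transcription factor of cytotrophoblast, fell by 0.43 on the log2 scale (adjusted p = 0.00976), the integrin ITGA6 fell from 508 ± 34 to 294 ± 16 TPM in macTSC#2 and from 508 ± 48 to 339.9 ± 25 TPM in macTSC#4, and the growth factor receptor FGFR2 changed by -1.47 ± 0.069 (SE). TP63 did not pass the test in macTSC#4 alone (adjusted p = 0.0655). CDX2 was not tested, with group means at or below 0.0106 TPM. Of 32 tested members, 7 rose, 9 fell and 16 did not pass the test, with 19 past the threshold when adjusted over the list alone, and the set was not called (camera, adjusted p = 0.921).

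Most tested members of the extravillous trophoblast list fell with CHIR99021. MMP12, a metalloproteinase that degrades elastin, fell from 145 ± 8.0 to 7.63 ± 0.28 TPM (SD, n = 2) in macTSC#2 and from 764 ± 11 to 89.3 ± 2.9 TPM in macTSC#4, and SERPINE1, the inhibitor of plasminogen activators, fell from 2874 ± 18 to 422 ± 6.7 TPM and from 2938 ± 230.4 to 641 ± 20.4 TPM. The aminopeptidase LVRN changed by -1.99 ± 0.10 (SE), and the protease inhibitor SERPINE2 by -1.96 ± 0.13 (SE). Fibronectin FN1 (-1.25), the fibronectin receptor subunit ITGA5 (-1.56) and the proteases HTRA1 (-1.79) and PCSK6 (-1.60) fell as well. ASCL2, a transcription factor of this lineage, fell in the mean of both lines (-0.45), from 70.2 to 44.0 TPM in macTSC#2 and from 47.3 to 39.8 TPM in macTSC#4. Of 31 tested members, 4 rose, 24 fell and 3 did not pass the test, with 28 past the threshold when adjusted over the list alone. Those that rose in the mean of both lines were FSTL1 (0.71), NOTCH1 (0.46), MMP2 (0.34) and LPCAT1 (0.26), MMP2 without passing the test in macTSC#4 (0.096). By line, only 2 members rose and 19 fell in macTSC#2, and 1 rose and 21 fell in macTSC#4. The median change of the list was -0.85, and the set stood lower than other genes (camera, adjusted p = 4.82e-10; adjusted p = 0.32 with an estimated correlation).

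Markers of other cell types moved beside this list, and beside the falls of the Wnt ligand, YAP, TGF-beta and glycolysis lists. Of 5 tested fibroblast and stroma genes, 3 fell, namely LUM (-1.75), SPARC (-0.83) and COL3A1 (-0.39), while COL1A2 (-0.13) and TWIST1 (0.14) did not pass the test. COL1A1 and DCN, abundant in fibroblasts, stood at or below 0.751 TPM in the mean of every group, against 345 TPM of COL3A1 in macTSC#4 without CHIR99021. All 3 tested endothelial genes fell, PECAM1 by 1.66, ESAM by 1.26 and EGFL7 by 0.62 on the log2 scale, with 2 of them past the test in macTSC#2 alone and 3 in macTSC#4 alone. Of 4 leukocyte genes, CSF1R fell (-1.54) and the others did not pass the test. Of 7 amnion genes, ISL1 (1.53), PITX1 (1.80) and HEY1 (1.09) rose in the mean of both lines. VTCN1 (-0.81), GABRP (-0.49) and MEIS1 (-0.46, with -0.16 in macTSC#2, not past the test) fell in that mean. By line, 3 amnion genes rose and 1 fell in macTSC#2, and 2 rose and 3 fell in macTSC#4, with GABRP and HEY1 given by line below. Of the 2 tested genes of mesoderm and endoderm, GATA6 rose (0.48; 0.15 in macTSC#4, not past the test) and MIXL1 did not pass (-0.13), and no pluripotency marker reached the level needed for a test. Of 6 mitochondrial mRNAs, ND1 rose (0.16) and the others did not pass the test.

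Genes of TGF-beta, BMP and YAP signalling fell for the most part. IGFBP3, a binding protein of insulin-like growth factors, fell from 2575 ± 56 to 427 ± 4.8 TPM (SD, n = 2) in macTSC#2 and from 4804 ± 48 to 1344 ± 36 TPM in macTSC#4. The coagulation factor receptor F3 changed by -2.09 ± 0.066 (SE), the matricellular protein CCN2 by -1.55 ± 0.090 (SE) and the ligand TGFB2 by -1.36 ± 0.069 (SE). Of 21 tested YAP targets, 0 rose, 13 fell and 8 did not pass the test, and 13 passed when adjusted over the list alone (camera, adjusted p = 4.92e-05; adjusted p = 0.32 with an estimated correlation). Of 17 tested genes of the BMP and TGF-beta response, 4 rose, 12 fell and 1 did not pass the test, with 16 past the threshold when adjusted over the list alone (camera, adjusted p = 0.00796; adjusted p = 0.32 with an estimated correlation). The members that rose included the ligand BMP4, from 1.81 ± 0.080 to 6.35 ± 0.36 TPM in macTSC#2 and from 9.49 ± 1.1 to 44.6 ± 1.3 TPM in macTSC#4, and its transcriptional target ID2 (1.71 ± 0.074, SE). NOG, a secreted BMP antagonist, fell by 1.68 on the log2 scale. Other BMP targets of this list fell, namely ID1 (-0.57), ID3 (-0.55), SMAD6 (-0.42) and SMAD7 (-0.22), although ID1 (-0.082) and SMAD6 (-0.062) did not pass the test in macTSC#4. SERPINE1 stands on the extravillous and the TGF-beta list, and CCN2 and TGFB2 on the TGF-beta and the YAP list.

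Some cell cycle genes rose with CHIR99021. CCNE1, a cyclin of S phase entry, rose from 70.3 ± 0.58 to 108 ± 0.86 TPM (SD, n = 2) in macTSC#2 and from 54.4 ± 1.1 to 79.2 ± 0.19 TPM in macTSC#4, thymidylate synthase TYMS rose by 0.39 ± 0.029 (SE), the chromatin remodeller HELLS by 0.39 ± 0.046 (SE) and the replication factor GINS2 by 0.37 ± 0.057 (SE). MKI67, a marker of proliferating cells, had a log2 fold change of 0.020 ± 0.095 (SE) and an adjusted p of 0.892. Without single libraries it ran from -0.0855 to 0.126, the ends being those without replicate 1 or replicate 2 of macTSC#4 without CHIR99021. Of 33 tested members, 17 rose, 3 fell and 13 did not pass the test, with 20 past the threshold when adjusted over the list alone (camera, adjusted p = 0.00216; adjusted p = 0.32 with an estimated correlation). Of 16 genes of growth arrest, 2 rose, 8 fell and 6 did not pass the test, with the retinoblastoma family members RBL2 (-0.77) and RB1 (-0.72) among those that fell and 10 past the threshold when adjusted over the list alone (camera, adjusted p = 0.20). In cholesterol synthesis, 11 of 22 tested genes rose and none fell, with SQLE (0.51), HMGCS1 (0.46) and the rate-limiting reductase HMGCR (0.36) among them and 13 past the threshold when adjusted over the list alone (camera, adjusted p = 0.000693; adjusted p = 0.32 with an estimated correlation).

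In glycolysis and the hypoxia response, EGLN3, a prolyl hydroxylase induced by hypoxia, fell from 175 ± 7.1 to 50.7 ± 4.2 TPM (SD, n = 2) in macTSC#2 and from 122 ± 0.31 to 37.7 ± 2.4 TPM in macTSC#4, and PDK1 (-1.19 ± 0.057, SE) and NDRG1 (-1.09 ± 0.035, SE) fell with it. Among the other members, PFKFB4 (0.45), PFKM (0.40), EGLN1 (0.26) and GAPDH (0.15) rose and BNIP3L (-0.88), VEGFA (-0.65) and PGAM1 (-0.27) fell. Of 23 tested members, 5 rose, 11 fell and 7 did not pass the test, with 17 past the threshold when adjusted over the list alone (camera, adjusted p = 0.0416; adjusted p = 0.32 with an estimated correlation). This call was also lost with median-of-ratios scaling (adjusted p = 0.0852), without replicate 2 of macTSC#2 without CHIR99021 (0.0616), and without replicate 1 of macTSC#4 with (0.0521) or without CHIR99021 (0.0738).

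The remaining lists were not called as sets by camera with all libraries. Of 10 Notch genes, 2 rose, 5 fell and 3 did not pass the test, with HEY1 (1.09) and HES4 (0.90) higher and the ligands JAG1 (-0.89) and JAG2 (-0.59) lower (7 adjusted over the list alone; camera, adjusted p = 0.247). Of 22 stress response genes, 7 rose, 7 fell and 8 did not pass the test, with HERPUD1 (-1.57) and CRELD2 (-0.82), induced by unfolded proteins, lower and the asparagine synthetase ASNS (0.58) higher (15 adjusted over the list alone; camera, adjusted p = 0.893). Of 13 immediate early genes, 2 rose, 7 fell and 4 did not pass the test, with the phosphatase DUSP1 (-1.67) and the transcription factors KLF4 (-0.78) and JUNB (-0.55) lower (9 adjusted over the list alone; camera, adjusted p = 0.0848). That set passed without replicate 2 of macTSC#4 with CHIR99021 (adjusted p = 0.0489). With all libraries its adjusted p was 0.32 with an estimated correlation. Of 13 interferon response genes, 2 rose, namely IFI6 (1.49 ± 0.091, SE) and ISG15 (0.82 ± 0.25, SE), and 1 passed when adjusted over the list alone (camera, adjusted p = 0.243). The ISG15 call (adjusted p = 0.040) was lost without a filter on low values (adjusted p = 0.0842). Of 12 imprinted genes, 5 rose, 4 fell and 3 did not pass the test, with 9 past the threshold when adjusted over the list alone. IGF2 fell from 1627 ± 72 to 841 ± 49.6 TPM (SD, n = 2) in macTSC#2 and from 1162 ± 280.4 to 597 ± 15 TPM in macTSC#4. PHLDA2, which restrains placental growth, rose in macTSC#2 (1.47) and did not pass the test in macTSC#4 (0.12, adjusted p = 0.562; adjusted p of the difference = 0.0285). The median of the imprinted list was 0.034 and its mean -0.074, opposite in sign (camera, adjusted p = 0.961). Of 21 genes of oxidative phosphorylation, 4 rose, 1 fell and 16 did not pass the test, with the complex I subunit NDUFS3 (0.28) the most changed (4 adjusted over the list alone; camera, adjusted p = 0.471).

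**Figure D2:**
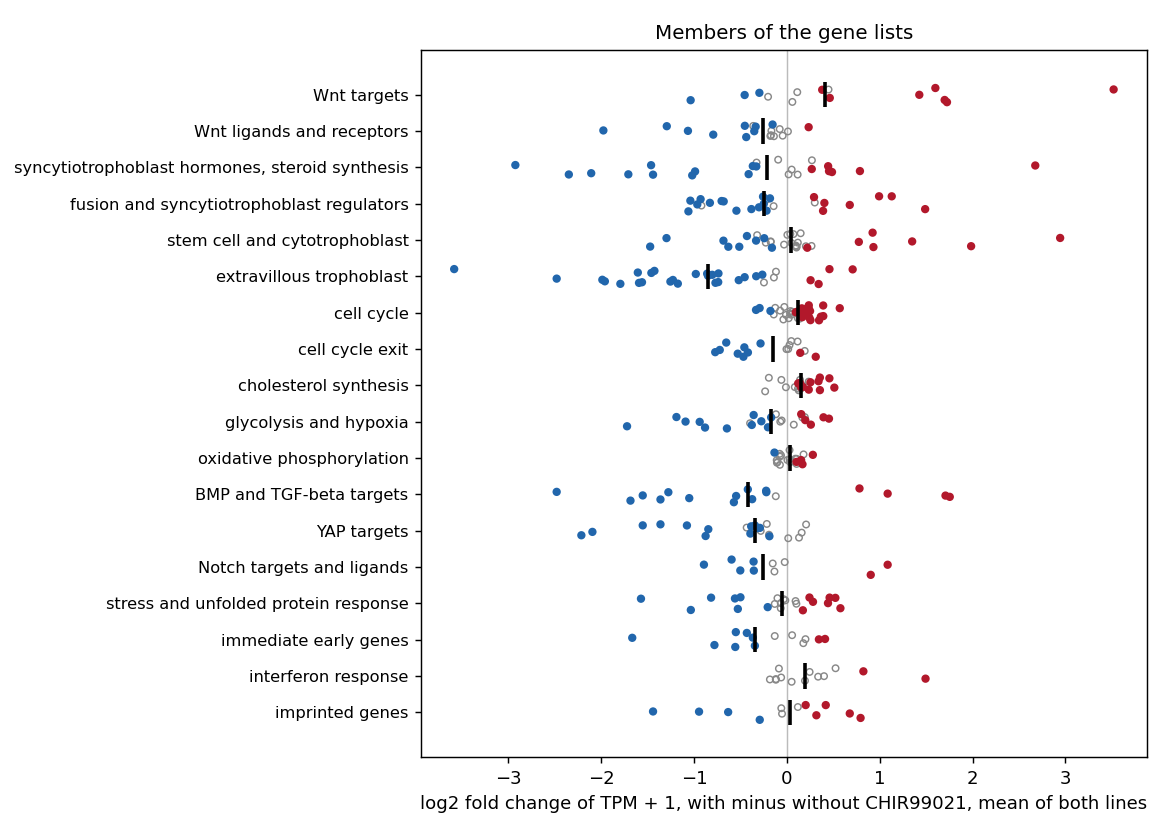
Log2 fold change of TPM + 1 with minus without CHIR99021, mean of both lines, for each tested member (point) of the 18 lists, filled red or blue where the member rose or fell past an adjusted p of 0.05, open where it did not, with a black bar at the list's median. The extravillous trophoblast list lies lowest, with a median of -0.85, and the Wnt target list holds the largest rise, TNFRSF19 at 3.52.

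By size of change in the mean of both lines, among genes with a symbol that moved the same way in each line, TNFRSF19 rose most. After TNFRSF19 (3.52 ± 0.069, SE) came the zinc finger gene ZNF703 (3.37 ± 0.10, SE), the peptidylarginine deiminase PADI4 (3.37 ± 0.077, SE), the transcription factor SP6 (3.25 ± 0.055, SE) and PAGE4. They were followed by ENDOU, the amino acid transporter SLC7A8 (2.57), the ubiquitin ligase RNF182 (2.52), the T-box factor TBX2 (2.51) and the kinase HUNK (2.45). SP6 rose from 13.5 ± 0.67 to 152 ± 1.0 TPM (SD, n = 2) in macTSC#2 and from 8.34 ± 0.79 to 79.3 ± 4.1 TPM in macTSC#4. The largest falls were those of RGS4, a regulator of G protein signalling (-4.09 ± 0.094, SE), MMP12, the collagenase MMP1 (-3.43 ± 0.048, SE), the myosin light chain MYL3 (-3.13 ± 0.14, SE) and ANGPTL7 (-2.93 ± 0.13, SE). INSL4, the protease HTRA3 (-2.90), the smooth muscle actin ACTA2 (-2.53), SERPINE1 and ADAMTS15 (-2.47) followed. MMP1 fell from 2487 ± 11 to 142 ± 3.2 TPM in macTSC#2 and from 5865 ± 370.0 to 877 ± 63 TPM in macTSC#4. ACTA2 has close actin paralogs, and the sharing of reads between them was not examined here.

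Counted over all 16902 tested genes, limma called 6004 for the mean effect at an adjusted p under 0.05, 2765 higher and 3239 lower with CHIR99021. This balance was not stable, being 3446 higher and 3054 lower with upper-quartile scaling, and 3038 and 3056 without replicate 2 of macTSC#4 without CHIR99021. With an absolute log2 fold change of 1 or more as well, 579 passed, 135 higher and 444 lower. Of the 18 lists tested, 8 passed, 3 upward and 5 downward, and none did with an estimated correlation (lowest adjusted p = 0.32). At an unadjusted p under 0.05, 1 list, that of extravillous trophoblast, passed with an estimated correlation. The lists not called by camera split by fry. Those of hormones (adjusted p = 1.38e-05), fusion (0.00208), growth arrest (0.000494), stress (0.000494), immediate early genes (0.000494) and Notch (0.0105) passed fry. Those of stem cells (0.698), oxidative phosphorylation (0.476), interferon response (0.149) and imprinted genes (0.129) did not. With 35.5% of all tested genes called, a pass by fry does not set a list apart from other genes. The stress list passed it with 7 members higher and 7 lower. The authors' deposited table called 121 genes higher and 300 lower. Of these 421 calls in the authors' deposited table, 384 were among the genes tested here. All 384 were called here in the same direction at any fold change, and 322 with an absolute log2 fold change of 1 or more. The authors' calls left out genes of smaller change, such as SDC1 (-0.96, DESeq2 adjusted p = 5.9e-05). By its DESeq2 adjusted p alone, that table held 3075 genes under 0.05, of which 2926 were called here. Of the 579 genes past both thresholds here, 257 were not called in the authors' deposited table, which gave each of them an absolute log2 fold change of 1 or less. For 189 of the 257, its DESeq2 adjusted p was 0.05 or more or was not given. Not called there were RGS4 (-0.69, adjusted p = 0.0544), MMP12 (-0.99, 0.0119), ANGPTL7 (-0.24, 0.494), ACTA2 (-0.68, 0.109), SERPINE2 (-0.49, 0.265) and CGA (-0.50, 0.301), among others. Those 257 differed more between the lines (median absolute log2 difference 1.18) than the 322 shared ones (0.43), and 211 of them lost their call in a fit without a term for the line, chosen after the data were seen.

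Within each line, CHIR99021 changed 4186 genes in macTSC#2, 1911 higher and 2275 lower, and 3796 in macTSC#4, 1597 higher and 2199 lower. With upper-quartile scaling the balance turned over in macTSC#2, 2366 higher and 2270 lower, and was 1955 and 2085 in macTSC#4. AXIN2 rose by 1.27 ± 0.062 (SE) in macTSC#2 and by 1.58 ± 0.062 (SE) in macTSC#4, TNFRSF19 by 3.69 ± 0.098 (SE) and 3.35 ± 0.098 (SE), and RGS4 changed by -4.03 ± 0.13 (SE) and -4.15 ± 0.13 (SE). 1075 genes were called higher in both lines, against 181 for independent lists, and 1485 lower in both, against 296. In contrast, 21 were called in opposite directions. Of the genes called in macTSC#2, 93.4% had the same sign in macTSC#4. Across all tested genes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson's r = 0.569 and Spearman's rho = 0.573. The lines share no libraries in these contrasts, but both use the same estimate of a gene's variance. Independent lists may therefore understate the overlap to be expected. Of the 18 lists, 8 passed camera in macTSC#2 and 7 in macTSC#4, where that of glycolysis and hypoxia did not pass (adjusted p = 0.24), and none did with an estimated correlation (lowest adjusted p = 0.313 and 0.391; 2 and 2 lists at an unadjusted p under 0.05). Leaving out any 1 of the macTSC#2 libraries brought the count in that line to 2146 to 2500, and leaving out replicate 1 or 2 of macTSC#4 with CHIR99021 brought that in macTSC#4 to 1890 or 1634. With only the libraries of macTSC#4 in the fit, 1099 genes were called in that line, and 3977 in macTSC#2 with only its own. The counts from all 8 libraries rest on 1 variance per gene for both lines, so they do not reflect each line's own spread. The macTSC#4 libraries without CHIR99021 differed most from each other, with a chi-square per degree of freedom of 33.8 against 7.58 to 9.66 in the other groups. Their difference, replicate 1 minus 2, ran with gene length at Spearman's rho = -0.242, against 0.11 to 0.146 in the other groups.

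The response differed between the lines for 167 genes by the test of the difference itself. NOTUM rose by 2.94 ± 0.078 (SE) in macTSC#2 and by 0.51 ± 0.078 (SE) in macTSC#4 (adjusted p of the difference = 0.00154), where it stood at 20.4 ± 0.16 TPM (SD, n = 2) without CHIR99021 against 4.21 ± 0.21 in macTSC#2. CCN4, a matricellular Wnt target, rose from 0.160 ± 0.11 to 7.62 ± 1.2 TPM in macTSC#4 and stood at 0.0969 ± 0.063 TPM with CHIR99021 in macTSC#2. MYOCD, a coactivator of smooth muscle genes, rose from 3.14 ± 0.0093 to 13.5 ± 1.0 TPM in macTSC#4, while its 0.21 in macTSC#2 did not pass the test. The smooth muscle actin ACTG2 and the gene LRRC49 fell more in macTSC#2 (-3.04 and -2.42) than in macTSC#4 (-1.14 and -0.88). TGFBI, an extracellular matrix protein, the glutamate transporter SLC1A1 and AGR3 fell in macTSC#4 (-2.38, -2.35 and -2.62) and did not pass the test in macTSC#2. There SLC1A1 had 0 to 19 and AGR3 1 to 12 reads per library. The reads of SLC1A1 fell in macTSC#2 too, from 18 and 19 without to 2 and 0 with CHIR99021. In a voom fit on reads the difference of SLC1A1 was 1.44 (adjusted p = 0.557) in place of -2.06, while CCN4 (4.30), MYOCD (1.28) and AGR3 (-2.23) kept the sign of their differences (2.80, 1.59 and -2.49) and missed the threshold (adjusted p = 0.0759, 0.11 and 0.327). NREP rose in macTSC#2 (0.66) and fell in macTSC#4 (-1.45). MMP1, MMP12 and SERPINE1 fell in both lines and more so in macTSC#2 (adjusted p of the difference = 0.00739, 0.010 and 0.0415).

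Of the 167 genes, 123 had effects of the same sign in both lines, 12 were called in both lines with opposite signs, and 119 had the larger absolute change in macTSC#2. Of the 18 lists, 6 differed between the lines by camera. Taken as macTSC#4 minus macTSC#2, the effect stood lower for the Wnt target list, where 1 member of 14, NOTUM, passed the test (camera, adjusted p = 0.0205), and for the imprinted list, with 2 of 12 lower (0.0205). It stood higher for the extravillous list, with 6 members higher and 1 lower of 31 (0.0205), the YAP list, with 2 of 21 higher (0.0306), the glycolysis list, with 1 of 23 higher (0.00626), and the cholesterol list, with 0 of 22 past the test (0.0245). Adjusted over the list alone, 5, 4, 13, 5, 1 and 0 members passed in these lists. No list passed with an estimated correlation, where the lowest adjusted p was 0.328 and 1 had an unadjusted p under 0.05. Beside these lists, the stromal LUM (-2.21 in macTSC#2 and -1.28 in macTSC#4) and the endothelial ESAM (-1.57 and -0.96) fell less in macTSC#4, and the amnion genes GABRP (0.0028 and -0.99) and HEY1 (1.83 and 0.35) had lower effects there (adjusted p of the difference = 0.0226, 0.033, 0.0189 and 0.0237). The count of 167 moved with single libraries. It was 296 and 89 without replicate 1 or 2 of macTSC#4 without CHIR99021, and 0 to 2 without any single library of the other groups, where limma counted 1741 to 1876 at an unadjusted p under 0.05 against 2210 with all libraries. The voom fit called 530 and median-of-ratios scaling 289, and upper-quartile scaling, the other filters and a pseudocount of 0.1 gave 113 to 230.

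**Figure D3:**
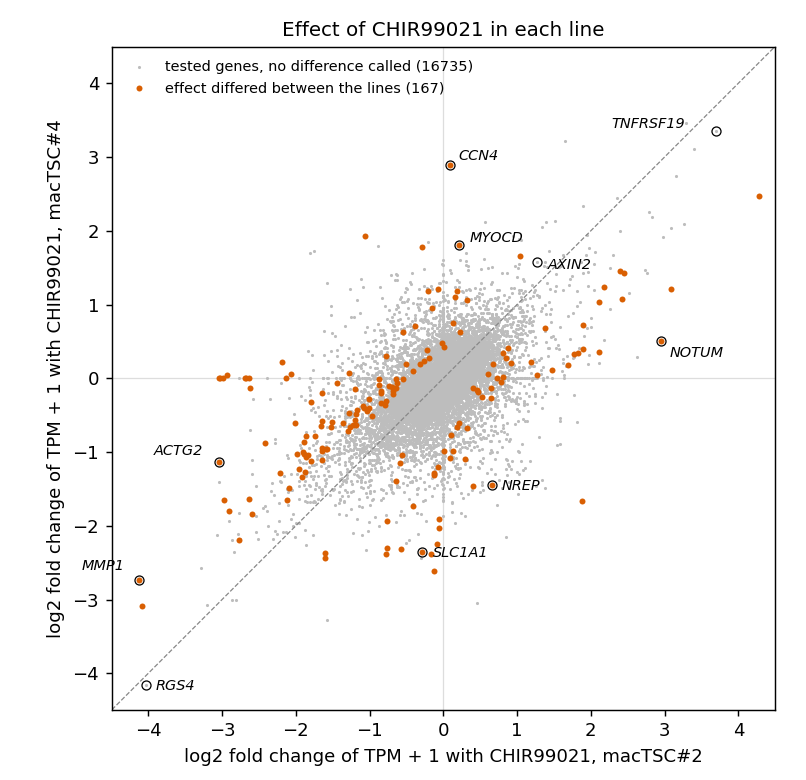
Log2 fold change of TPM + 1 with CHIR99021 in macTSC#4 against that in macTSC#2 for the 16902 tested genes (grey), with the 167 genes whose effect differed between the lines in orange and the dashed line marking equal effects. AXIN2, TNFRSF19 and RGS4 lie close to that line, and NOTUM (2.94 in macTSC#2, 0.51 in macTSC#4) and CCN4 (0.088 and 2.89) lie far from it.

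The lines themselves differed at 8150 genes in the mean of both treatments, 3780 higher and 4370 lower in macTSC#4. ANGPTL7 stood at 2824 ± 39.9 TPM (SD, n = 2) without CHIR99021 in macTSC#4 and at 12.5 ± 2.6 in macTSC#2. ALDH1A3, which makes retinoic acid, and CRABP2, which binds it, stood at 333 ± 9.0 and 199.6 ± 11 TPM in macTSC#4 against 0.259 ± 0.038 and 0.106 ± 0.0081 in macTSC#2. The collagens COL5A2 (6.79 ± 0.063, SE, on the log2 scale) and COL18A1 (5.86 ± 0.055, SE) were higher in macTSC#4. RPL37 (ENSMFAG00000043057), a protein of the large ribosomal subunit, stood at 628 ± 1.5 TPM in macTSC#2 and at 30.8 ± 1.6 TPM in macTSC#4 without CHIR99021, and the authors' counting could divide its reads with near-identical copies. ETNPPL (-3.82), CLVS2 (-3.73), the meiotic recombinase DMC1 (-3.23) and the gastric lipase LIPF (-3.11) were also lower in macTSC#4. CGA was higher in macTSC#4 by 2.43 ± 0.28 (SE). The extravillous list stood higher in macTSC#4, with 19 members higher and 4 lower of 31 (camera, adjusted p = 4.90e-05), and the glycolysis (15 of 23 lower; 0.0426) and cholesterol lists (15 of 22 lower; 0.0497) stood lower. Adjusted over the list alone, 24, 20 and 18 members passed, and each set had adjusted p = 0.594 with an estimated correlation. Fibroblast genes moved with the line as well, 4 of 5 higher in macTSC#4 and 1 lower, and so did mitochondrial mRNAs, 4 of 6 higher and 2 lower. All 3 endothelial genes were higher in macTSC#4, among them PECAM1 (1.40). Of 7 amnion genes, 3 were higher, namely VTCN1 (3.70), GABRP (2.75) and MEIS1 (1.39), and 1 was lower. Of 4 leukocyte genes, CD14 (0.71) was higher and LYZ (-0.62) and CSF1R (-1.08) were lower, and of 2 genes of mesoderm and endoderm MIXL1 was lower (-0.50). Of the 12 genes on the sex-linked list, only 2, the Y-linked TMSB4Y and NLGN4Y, were present by symbol, so the sex of the lines cannot be told from it. TMSB4Y stood at 1.73 ± 0.36 TPM in macTSC#2 and 1.72 ± 0.015 TPM in macTSC#4 without CHIR99021 (adjusted p = 0.91 for the lines). Its reads can be shared with the X-linked TMSB4X. NLGN4Y stood at or below 0.0186 TPM in every group mean.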

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

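The tests below were set before their results were seen, except the share of fibroblast genes, the comparison of RPL37 in reads and the choice of a voom fit, which came after the data were seen. The 167 genes whose CHIR99021 effect differed between the lines stand out by the test of that difference, and the 10 with the largest differences are given as macTSC#4 minus macTSC#2 on the log2 scale. The effect was higher in macTSC#4 for MIR103A2-201 (2.98), CCN4 (2.80), ACTG2 (1.90), MYOCD (1.59) and LRRC49 (1.54). It was lower for AGR3 (-2.49), NOTUM (-2.44), TGFBI (-2.21), NREP (-2.11) and SLC1A1 (-2.06). MIR103A2-201 rests on 0 to 8 reads per library, and SLC1A1 on 0 to 19 and AGR3 on 1 to 12 reads per library in macTSC#2. No group held enough libraries for a test of single outlying samples.

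Few reads as the whole cause of these differences were tested by the voom fit on whole reads. There 81.4% of the called genes (136 of 167) kept direction and call, past the bound of 50% set for the test. That fit called 530 genes in all and used median-of-ratios scaling, which alone called 289 on TPM, so kept calls cannot decide on few reads. With a pseudocount of 0.1, 106 of the 167 stayed called. Of the 10 named above, SLC1A1 turned in sign in the voom fit (1.44, adjusted p = 0.557). CCN4 (4.30), MYOCD (1.28), AGR3 (-2.23) and MIR103A2-201 (4.38) missed the threshold with their signs unchanged. Few reads stay open in particular for MIR103A2-201, with its 0 to 8 reads. The same holds for AGR3 and CCN4, with 1 to 12 and 2 to 14 reads per library in macTSC#2. SLC1A1 went from 18 and 19 reads without to 2 and 0 with CHIR99021 in macTSC#2, and from 1670 and 1456 to 258 and 273 in macTSC#4. Its reads thus fell in both lines and do not bear out a larger fall in macTSC#4. Levels that differ before treatment and converge with it could not be decided, since 61.1% of the called genes (102 of 167) differed less between the lines with CHIR99021 than without, between the bounds of 50% and 70% set for the test. Leaving out any single library outside macTSC#4 without CHIR99021 brought the count to 0 to 2, so the number of such genes is not well fixed. A difference in biology between the lines remains open as a hypothesis and was not tested.

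The fall of the extravillous trophoblast list (median log2 fold change -0.85) was set against 3 technical explanations. A shift of the TPM scale would move all genes, and their median change was -0.0040. Noise of genes near the floor was argued against by the 23 members with a mean of 10 TPM or more, whose median was -0.86, with 20 lower. A loss of fibroblasts or stromal cells would take their abundant transcripts along. COL1A1 and DCN reached at most 0.218% of the TPM of COL3A1 without CHIR99021, but LUM stood at 188 TPM in macTSC#2 and 213 in macTSC#4. COL1A1 and DCN were chosen after the values were seen, so their share cannot decide the question. The test first planned, the median TPM of 5 fibroblast genes (47.0 in macTSC#4 and 1.82 in macTSC#2), left it open. A response of the trophoblast cells to CHIR99021 is a candidate explanation beside such a loss, as a hypothesis found and tested on the same libraries. The set's adjusted p in camera was 0.32 with an estimated correlation.

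RPL37 was lower in macTSC#4 by 4.42 on the log2 scale. Lower mRNA of ribosomal proteins in general was argued against by the other 49 RPL and RPS genes, with a median difference of -0.082 and a lowest value of -0.88. Reads counted on a near-identical copy in 1 line remain a candidate explanation, since 2 genes without a symbol, MSTRG.13062 and MSTRG.13562, were higher in macTSC#4 by at least 50% of the TPM that RPL37 lost and 5-fold or more, although 8 genes in all met that bound and 4 its mirror image. In reads, MSTRG.10760 gained 56.5% of the loss of RPL37 with and 56.3% without CHIR99021, MSTRG.13062 gained 20.3% and 20.8%, and MSTRG.13562 63.9% and 218%, but FSCN1, PRSS12 and ALDH1A3, which are not ribosomal, also gained between 50% and 200% of the loss. The sequences of these genes were not analysed here, so such a copy, a variant of 1 line against the reference and a true difference between the lines stay open.

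Of the 35 splits of the 8 libraries into 4 and 4, 34 could be fitted beside the other factor. 1 split, the real one, gave as many genes as the 6004 of the mean CHIR99021 effect, with 167 as the highest of the others. Likewise, 1 split gave as many as the 8150 that differ between the lines, with 167 as the highest other. That highest split joins macTSC#2 with CHIR99021 to macTSC#4 without it, and so counts the genes whose effect differed between the lines. The other splits hold the real effect within their spread, which lowers their counts, so this comparison cannot exclude chance. Chance between separate cultures was not tested.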

How the results depend on the processing

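The voom fit and the fit without a line term were chosen after the data were seen, and the other alternatives before. The mean CHIR99021 effect gave 5119 to 6724 genes under scaling, filters, pseudocount, block, additive and voom fits and 4519 to 6575 without single libraries. It fell to 2005 without a line term, which leaves the difference between lines in the spread, and to 579 with an absolute log2 fold change of 1 or more. With that bound the other counts were 768 in macTSC#2, 598 in macTSC#4, 73 for the difference of effects and 1872 between the lines. The lines differed at 6668 to 8687 genes under the other alternatives. Leaving out single libraries gave 2146 to 5087 genes in macTSC#2, the lower counts of 2146 to 2500 without a library of that line, and 1634 to 4451 in macTSC#4, where 1890 and 1634 were counted without replicate 1 or 2 with CHIR99021. In such fits the lone library of a group is assumed to vary like the other groups. With only their own libraries, macTSC#2 gave 3977 genes and macTSC#4 1099. The fit of all 8 libraries gives both lines the same variance per gene, so its 4186 and 3796 are not counts on each line's own spread. The cause of the lower count in macTSC#4 was not tested. The difference of effects was least stable, with 289 genes under median-of-ratios scaling, 530 with voom, and 0 to 296 without single libraries; the cause was not tested. At an unadjusted p under 0.05, limma counted 2210 genes, and 1741 without replicate 2 of macTSC#2 without CHIR99021, where 0 passed the adjustment. Replicate numbers share only a number between groups, with correlations of deviations of -0.0691 to 0.0704. The replicate block gave 2 genes for the difference of effects, 5119 for the mean effect, 3244 in macTSC#2, 2714 in macTSC#4 and 7373 between the lines. With an estimated correlation, 0 lists passed camera (1 at an unadjusted p under 0.05). A higher correlation was not needed for this. The glycolysis list, estimated at 0.00229 against the preset 0.01, went from an unadjusted camera p of 0.0185 to 0.0641. Failing in this setting therefore does not single out a list, and the cause was not tested. The correlation of the lines' effects was 0.513 to 0.546 without single libraries and 0.644 with the stricter filter; the cause was not tested. Of 110 called results of named genes, 95 kept direction and call in all 15 alternatives. The others were the 10 differences of effects and the mean effects of ATP5F1C, CYC1, NDUFB10, GADD45B and ISG15. The block ended 11 of these calls and brought that of GCM1 (adjusted p = 0.0446), and without a filter CYP19A1 was called (0.00369). Signs changed for MKI67 (-0.00844, -0.0262 and -0.0855 without replicate 1 of macTSC#2 with CHIR99021, replicate 2 of macTSC#2 without it or replicate 1 of macTSC#4 without it, with 0.126 as the highest), for TMSB4Y between the lines (-0.0555 and -0.0451 without replicate 1 of macTSC#2 with or without CHIR99021, 0.102 as the highest), neither of them called, and for SLC1A1 with voom (1.44), which has 0 to 19 reads per library in macTSC#2; the cause was not tested. Planned count-based tests and their normalisations were not run, because the file holds TPM. Depth limits genes near 1 TPM, where few reads stand behind a value.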

Other observations

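The test below was written before its result was seen, but its gene list was drawn up after ACTA2, MYL3, ACTG2 and MYOCD had been named by the rule, and leaves them out. Most tested genes of the contractile apparatus fell with CHIR99021. CALD1, which binds actin and myosin, fell from 503 ± 0.058 to 187 ± 9.3 TPM in macTSC#2 and from 825 ± 26 to 391 ± 30.4 TPM in macTSC#4 (SD, n = 2; log2 fold change -1.25). The kinase MYLK (-1.58), the myosin light chain MYL9 (-0.83), the actin-binding TAGLN (-0.61), PDLIM7 (-0.62) and LMOD1 (-0.88) fell as well, and so did the coactivator MRTFA (-0.43). SRF, the transcription factor that MRTFA binds, rose (0.21), as MYOCD did in macTSC#4. FLNA (-0.20), CNN1 (0.21) and MYH11 (-0.17) did not pass the test. In all, 10 of 14 tested genes of the 21 on the list fell and 1 rose. The stromal genes LUM (-1.75) and SPARC (-0.83) and the endothelial genes PECAM1 (-1.66) and ESAM (-1.26) fell beside them.

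The hypothesis was that contractile genes fall with CHIR99021 beyond those named by the rule, with a median log2 fold change under -0.5 and a directional fry p under 0.05. The median was -0.485 and missed its bound, while limma's fry, which asks whether the genes move one way and not whether they differ from other genes, passed its bound. The hypothesis therefore stays undecided. The members moved unequally, and how they do so in relation to YAP or TGF-beta signalling was not tested.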
